A study of Homo sapiens with 58 samples.

How the data were processed

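Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out in G401 cells, an established human rhabdoid tumor line that lacks the SWI/SNF subunit SMARCB1. The 58 samples covered cells with a control hairpin (shCTRL), cells with a hairpin against DCAF5 (shDCAF5), and cells with degradation-tagged DCAF5 (dTAG) kept in DMSO or treated with 500 nM of the degrader V-1, with 4 h as the time in the labels. A processed list was used for 46 samples. The 12 others, which are 10 inputs and 2 BRD9 samples of shDCAF5 cells, were not analysed here.

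Per the submitters' processing notes, Trim Galore 0.4.4, BWA, SAMtools, bedtools 2.24.0 and MACS2 were used, and the builds named were hg19, GRCh37.p13 and dm6. The role of dm6, the caller settings and any merging of reads are not given in the sources used here. The deposited lists hold hg19 coordinates per the file names, 1 list per library. The 42 narrow lists cover ARID1A, SMARCC1 (BAF155), SMARCA4 (BRG1), BRD9, p300, H3K27ac and H3K4me3. In these lists the authors gave each peak a fold enrichment, which is a ratio over the local background, and a −log10 p and a −log10 q. The lowest −log10 q of any narrow list was 1.30. The 4 H3K4me1 lists were deposited as islands of another caller, named SICER in the file names, and hold read counts of the ChIP and of the control per island, a fold ratio and a p-value with an adjusted p-value. Fold enrichments and scores are the authors' values and were used to rank, filter or describe peaks within a list. Across lists, fold enrichments were averaged to order and describe the named regions. With p-values or read counts they also gave the background pileups and H3K4me1 library ratios below, which are compared between lists. Peaks outside chromosomes 1 to 22 and X were left out, at most 100 per list.

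Labels set every group. Some names inside the deposited lists differ from the labels: the peaks of shDCAF5 ARID1A replicates 2 and 3 carry names that read shCTRL, the replicate 1 ARID1A lists name another antibody supplier than the labels, the dTAG H3K27ac peaks carry names with another time than the 4 h of the labels, and BRD9 replicate 2 carries another replicate number. The labels were kept. Library numbers divide the SWI/SNF lists into replicate 1, from one series of library numbers, and replicates 2 and 3, from another. For the distal share, the SWI/SNF peak number and the 2 sides, values within 1 or both series are printed beside the pooled ones. Nothing in the labels says that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical. Lists of different subunits with the same replicate number may share chromatin, and a test that takes them as independent then gives p-values that are too small.

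Promoter-like regions were defined without annotation as merged H3K4me3 peaks called in at least 2 of the 4 H3K4me3 lists. They numbered 23540 and covered 58.4 Mb. A peak was called distal when it overlapped none of them by 1 bp or more. H3K4me1-marked parts of the genome were those covered in at least 2 of the 4 H3K4me1 lists, 413.8 Mb. SWI/SNF regions were unions of the overlapping peaks of the 17 shRNA lists of ARID1A, SMARCC1 and SMARCA4. Of 189035 merged regions, 95432 were called in at least 2 lists and were tested. For each, the number of lists with a peak was compared between 9 shDCAF5 and 8 shCTRL lists by a two-sided Fisher exact test with Benjamini-Hochberg adjustment and a threshold of 0.05. Peak numbers (log2) and distal shares were compared by two-sided exact permutation of the genotype labels, within antibody and over the 3 subunits together. Targets with 3 lists against 3 cannot go below an exact p of 0.1, and those with 2 against 2 cannot go below 0.333. The tests, the thresholds, most alternative settings and the rule for naming gained and lost regions were set before the data were examined. The rule takes the 5 regions on each side with the smallest p, then the largest difference in lists, then the highest mean fold enrichment.

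The region test was tested on simulated data with the real list lengths and 95432 regions. It recovered 100% of 200 regions called in all shDCAF5 and no shCTRL lists, 22.5% of 200 regions with call rates of 90% and 10%, and 2.5% of those with rates of 80% and 20%. These shares depend on how many changed regions are planted, since the adjustment needs enough regions at the smallest p: the 42 real regions called in all shDCAF5 and no shCTRL lists had an adjusted p of 0.0753 and were not called. Among 94832 simulated unchanged regions it called 0 at the adjusted threshold, and an unadjusted p under 0.05 was reached by 618 in the direction of shDCAF5 and 446 in the direction of shCTRL. The simulation dealt calls to the lists independently, by list length alone, without the 2 series or shared chromatin. Its counts are therefore not the error level of the real lists, whose splits gave up to 11011 regions on one side. Because the adjusted test called no real region, regions with an unadjusted p under 0.05 were used to describe the 2 directions, in the overlaps with marks and V-1 and in the naming of regions. This choice was made after the data were seen.

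Read depth is not stated in narrow lists. It was in part recovered from the arithmetic of the caller, in which the fold enrichment is the summit pileup plus 1 over the background plus 1 and the p-value is the Poisson tail of the pileup. In 27 of the 42 narrow lists a whole-number pileup gave the deposited −log10 p within 0.002 for at least 99% of the peaks examined, and the lowest recurring background pileup was taken as a measure of depth. It reflects the smaller of ChIP and control and the fragment length, so it is only a rough guide.

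No gene was assigned to a region: the gene table at hand is of another build than the lists, and no coordinates were converted. The 18 gene lists set before the data were examined were therefore not tested. Alternatives were a −log10 q of at least 5, each replicate left out, the replicate number as a block, the lists of replicates 2 and 3 alone, equal list length (the 22948 peaks with the highest −log10 p of each SWI/SNF list, the length of the shortest), other minimum numbers of lists, 500 bp regions around summits, and covered length in place of peak number. Added after the data were seen were leaving out the shDCAF5 ARID1A lists named shCTRL, leaving out the 2 lists of lowest background, peaks that cover at least 50% of the region, and equal list length without shCTRL SMARCC1 replicate 2. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.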

Results

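The occupancy of the SWI/SNF chromatin remodeling complex was profiled in G401 rhabdoid tumor cells with normal or reduced DCAF5, a substrate receptor of a cullin-RING ubiquitin ligase. The title of the series names the question, which is whether loss of DCAF5 stabilizes SWI/SNF in cells that lack SMARCB1. ARID1A, the large subunit of the canonical complex, and SMARCC1, a core scaffold subunit, had 3 shCTRL and 3 shDCAF5 lists. SMARCA4, the ATPase, had 2 and 3. The acetyltransferase p300 had 3 and 3, the promoter mark H3K4me3 and the enhancer-associated mark H3K4me1 had 2 and 2, and the activity mark H3K27ac had 1 and 2. BRD9, a subunit of the non-canonical complex, had 2 shCTRL lists. After acute degradation, each subunit had 1 DMSO and 1 V-1 list, and H3K27ac had 2 and 2.

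The share of SWI/SNF peaks at distal sites was higher on average in shDCAF5 cells, but with all peaks of each list the genotypes overlapped. ARID1A lists were 49.5% ± 13.99 distal in shDCAF5 and 45.5% ± 23.1 in shCTRL cells, and SMARCC1 lists 53.98% ± 16.6 and 41.4% ± 27.6 (SD, n = 3 and 3 each). SMARCA4 lists were 53.2% ± 23.2 and 46.3% ± 35.5 distal (SD, n = 3 and 2). The mean difference over the subunits was 7.86 percentage points (two-sided exact permutation p = 0.466), 16.1 in replicate 1 and -0.459 in replicates 2 and 3. This was the test set for the comparison, and it did not pass the threshold.

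With equal list length, one of the alternative settings, the genotypes were apart. The 22948 highest-ranked peaks that it keeps are 71.4% to 100% of the replicate 1 lists and 22.95% to 46.4% of the lists of replicates 2 and 3. Of these peaks, 36.8% ± 3.56 of ARID1A peaks were distal in shDCAF5 and 22.6% ± 3.96 in shCTRL cells (SD, n = 3 and 3). For SMARCC1 the shares were 32.9% ± 0.480 and 18.9% ± 7.39 (SD, n = 3 and 3), and for SMARCA4 25.8% ± 0.396 and 21.1% ± 5.23 (SD, n = 3 and 2). Every shDCAF5 list lay above every shCTRL list of its antibody, with SMARCA4 the closest at 25.3% and 24.8%. The mean difference was 10.96 points (exact permutation p = 0.00025, the smallest that the 4000 arrangements can give), 16.5 in replicate 1 and 7.60 in replicates 2 and 3 (exact permutation p = 0.00926, the smallest of 108 arrangements). Per subunit the exact permutation p was 0.1, the smallest possible. Of the other settings that kept all 17 lists, a -log10 q of at least 5 gave an exact permutation p of 0.319 and the replicate number as a block 0.25.

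**Figure D1:**
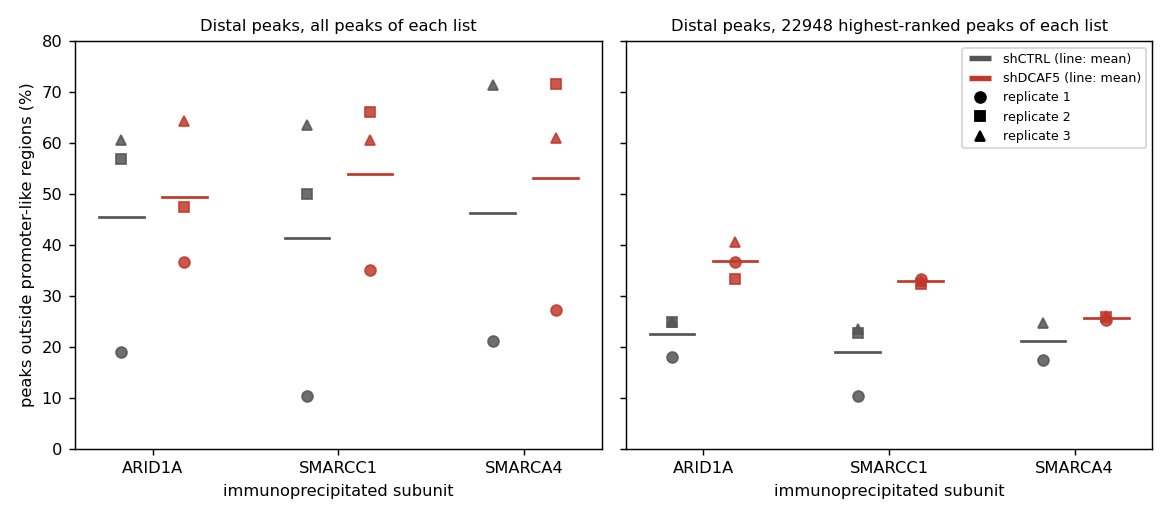
Share of SWI/SNF peaks outside promoter-like regions (%, vertical axis) per list, by subunit (horizontal axis), for all peaks (left) and for the 22948 highest-ranked peaks of each list (right); gray is shCTRL, red is shDCAF5, point shapes are replicates and lines are means. On the right all shDCAF5 lists lie above all shCTRL lists of their subunit (SMARCC1: at least 32.4% against at most 23.6%), and on the left the genotypes overlap.

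The number of SWI/SNF peaks did not differ by more than the spread between lists. ARID1A lists held 56725 ± 27227 peaks in shCTRL and 52310 ± 30889 in shDCAF5 cells (SD, n = 3 and 3), SMARCC1 lists 56380 ± 29687 and 70154 ± 36967 (SD, n = 3 and 3), and SMARCA4 lists 64173 ± 47806 and 68899 ± 34282 (SD, n = 2 and 3). The mean log2 difference was 0.11, with an exact permutation p of 0.780. Its direction turned when the lists of replicates 2 and 3 were taken alone (-0.0086326) or covered length was used (-0.033181). Replicate 1 lists held 22948 to 32124 peaks, and those of replicates 2 and 3 held 49455 to 99972. Within the second series, the recovered background pileup was 0.89 in shCTRL SMARCC1 replicate 2 and 1.34 in shDCAF5 ARID1A replicate 2, and 3.42 to 5.73 in the 6 other lists for which it could be recovered. Those shallow lists were the shorter of the pair of lists of their antibody and genotype in that series, with 66114 and 49455 peaks.

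Individual SWI/SNF regions were called more often in shDCAF5 than in shCTRL lists, mostly at distal, H3K4me1-marked sites, but none passed the adjusted test. Of the 95432 tested regions, 42 had a peak in all 9 shDCAF5 lists and no shCTRL list, and 0 had a peak in all 8 shCTRL lists and no shDCAF5 list. By Fisher's exact test with Benjamini-Hochberg adjustment 0 regions were gained and 0 were lost, with a lowest adjusted p of 0.0753. At an unadjusted p under 0.05, 4537 regions leaned to shDCAF5 and 576 to shCTRL, a ratio of 7.88. With equal list length the numbers were 3243 and 1446, a ratio of 2.243, and with replicates 2 and 3 alone they were 2886 and 487. Leaving out 1 list gave ratios from 5.73 (without shCTRL SMARCC1 replicate 1) to 56.5 (without shDCAF5 SMARCA4 replicate 1). The shCTRL side fell to 74 to 151 regions without any 1 of the shDCAF5 lists, or without shCTRL ARID1A replicate 2 or 3, SMARCC1 replicate 3 or SMARCA4 replicate 3. Part of this fall is set by the test. Of the 576 regions, 374 had peaks in 4 shCTRL and 0 shDCAF5 lists. That pattern no longer reaches an unadjusted p under 0.05 once any shDCAF5 list is left out. The shDCAF5 side fell to 2637 to 2852 without shDCAF5 ARID1A replicate 3, or SMARCC1 or SMARCA4 replicate 2 or 3. The test sets part of this fall too. Of the 4537 regions, 877 had peaks in 5 shDCAF5 and 0 shCTRL lists. That pattern no longer reaches an unadjusted p under 0.05 once 1 of those 5 lists is left out. The 4537 and 576 regions are called shDCAF5-side and shCTRL-side regions below. Distal regions made up 94.5% of the shDCAF5 side, 88.0% of the shCTRL side and 75.0% of the other tested regions. Distal H3K4me1-marked regions made up 86.8%, 77.1% and 63.7%. That marking needs 2 of the 4 H3K4me1 lists, so the 2 shDCAF5 lists alone can set it. With the shCTRL H3K4me1 lists the order was another. They overlapped 52.6% ± 3.45 of distal regions on the shDCAF5 side, 86.6% ± 1.95 on the shCTRL side and 77.7% ± 2.22 of the others (SD, n = 2). The distal share differed between the sides with an odds ratio of 2.34 (Fisher exact p = 3.67e-08, across regions, which are not independent replicates). The count of gained regions depended on the setting: 521 gained and 0 lost among the 59003 regions called in at least 4 lists, and 1304 gained and 142 lost among 31433 regions with equal list length. It also depended on 1 library. Without the library labelled shCTRL SMARCC1 replicate 2, 383 regions were gained and 0 lost.

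**Figure D2:**
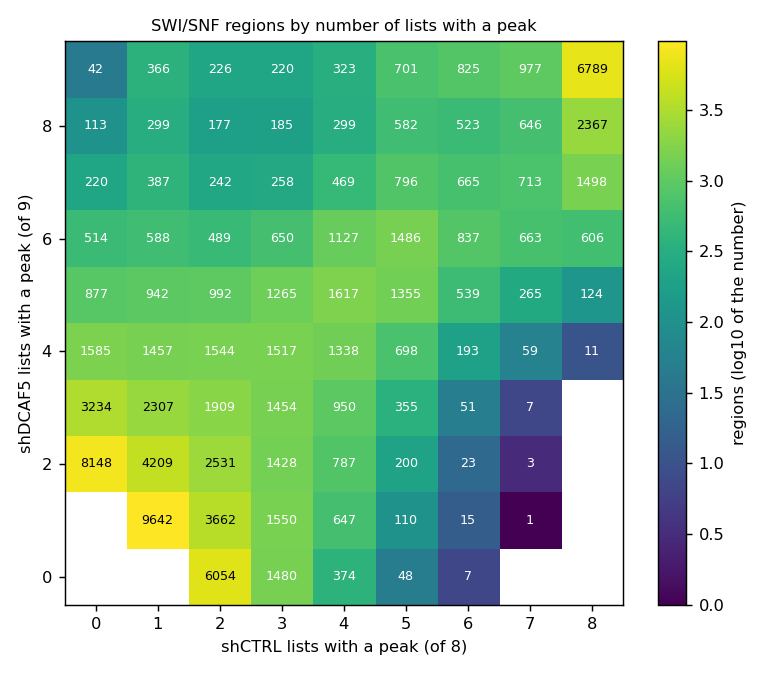
Number of tested SWI/SNF regions (number in each square, color on a log10 scale) by how many of 8 shCTRL lists (horizontal axis) and of 9 shDCAF5 lists (vertical axis) had a peak; regions called in fewer than 2 lists are not shown. The upper left corner, with all shDCAF5 lists and no shCTRL list, holds 42 regions, and the lower right corner holds 0.

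The library labelled shCTRL SMARCC1 replicate 2 had peaks in 48.0% of the shDCAF5-side regions. The 7 other shCTRL lists had peaks in 0.022% to 18.9% of them, and the shDCAF5 lists in 42.2% to 98.5%. Of the 366 regions called in all shDCAF5 lists and exactly 1 shCTRL list, this library was that list in 341. Every shCTRL mean of SMARCC1 given here includes it under its label.

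As no region was gained or lost, the naming rule was applied to the 2 sides. The 5 shDCAF5-side regions it named had peaks in 9 of 9 shDCAF5 and 0 of 8 shCTRL lists (Fisher exact p = 4.11e-05, adjusted p = 0.0753). Positions are in hg19. The first, on chromosome 9 from 82378856 to 82380094, was distal and H3K4me1-marked, with a mean fold enrichment of 8.19 over its lists. It was overlapped by both shDCAF5 H3K27ac lists and not by the shCTRL list, and was called in all 3 DMSO and all 3 V-1 lists. H3K4me1 islands overlapped it in 2 of 2 shDCAF5 and 1 of 2 shCTRL lists. The second, on chromosome 5 from 153664879 to 153667257, was promoter-like, with a mean fold enrichment of 8.01. It was overlapped by p300 peaks in 3 of 3 shDCAF5 and 0 of 3 shCTRL lists. The 1 shCTRL H3K27ac list and 2 of 2 shCTRL H3K4me1 lists also overlapped it, as did both shDCAF5 lists of each mark. The third, on chromosome 8 from 102368414 to 102369395 (mean fold enrichment 7.40), had H3K4me1 and H3K27ac in 2 of 2 shDCAF5 lists each and in no shCTRL list. The fourth, on chromosome 6 from 127347218 to 127348028 (7.38), and the fifth, on chromosome 3 from 183265660 to 183266516 (mean fold enrichment 7.34), were distal, with H3K4me1 in 2 of 2 shDCAF5 and 0 of 2 shCTRL lists. The fifth also had p300 in 2 of 3 shDCAF5 lists. Apart from the first, none of these regions was called in a DMSO or V-1 list.

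The 5 shCTRL-side regions named by the rule had peaks in 0 shDCAF5 and 6 shCTRL lists (Fisher exact p = 0.00226, adjusted p = 0.222). They lay on chromosome 4 from 98063462 to 98064145 and from 99923933 to 99924586, on chromosome 22 from 46710100 to 46710648, on chromosome 17 from 76242276 to 76244135 and on chromosome 8 from 6257155 to 6258155. Their mean fold enrichments were 3.84 to 4.52. The shCTRL H3K27ac list covered all 5, and both shDCAF5 H3K27ac lists covered 2 of them.

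Per subunit, regions called in every list of one genotype and no list of the other were more numerous for shDCAF5 with all lists. This direction turned when replicate 1 of shCTRL alone was left out, a setting that loosens the rule for shCTRL only. Over the 3 subunits together, 587 regions were called in all shDCAF5 and no shCTRL lists of replicates 2 and 3, and 35 were the reverse. In replicate 1 the numbers were 1881 and 610. ARID1A had 1528 such regions in shDCAF5 and 263 in shCTRL cells, SMARCC1 667 and 10, and SMARCA4 1353 and 212. With 500 bp regions around summits the numbers were 1657 and 367, 861 and 153, and 1812 and 445. With peaks covering at least 50% of the region they were 943 and 260, 519 and 5, and 544 and 135. For ARID1A, 94.2% of the shDCAF5 regions were distal, against 51.0% of the shCTRL regions and 16.9% of the 11561 regions called in every list. For SMARCC1 93.9% of the shDCAF5 regions were distal. For SMARCA4 the shares were close, 92.4% of the shDCAF5 and 90.6% of the shCTRL regions. Without shCTRL replicate 1 the numbers were 1529 and 6087 for ARID1A, 669 and 1773 for SMARCC1, and 1372 and 34533 for SMARCA4. SMARCA4 then had only 1 shCTRL list left. Without shDCAF5 ARID1A replicate 3 the ARID1A numbers were 1593 and 1820. Without shDCAF5 replicate 1 they were 4579 and 279 for ARID1A, 9001 and 10 for SMARCC1, and 9482 and 228 for SMARCA4. Each such setting asks fewer lists of 1 genotype to agree, so a turn under it does not compare the genotypes on equal terms. Without the library labelled shCTRL SMARCC1 replicate 2, SMARCC1 had 2138 and 32, without shCTRL SMARCC1 replicate 3 it had 1765 and 19, and without shCTRL SMARCA4 replicate 3, SMARCA4 had 6859 and 855. The shCTRL count of SMARCC1 was 59 and 29 without shDCAF5 replicate 2 or 3, and that of SMARCA4 was 532 without shDCAF5 replicate 2.

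Regions with peaks for all 3 subunits in the same replicate were mostly promoter-like in replicate 1. In shCTRL replicate 1 there were 13844, of which 7.08% were distal, and in shDCAF5 replicate 1 there were 12415, of which 27.8% were distal. In replicate 3 there were 35500 in shCTRL (45.3% distal) and 38180 in shDCAF5 cells (47.4% distal). shCTRL replicate 2 had no SMARCA4 list.

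The sites that leaned to shDCAF5 were also overlapped more often by enhancer-mark lists of shDCAF5 cells, but the H3K4me1 libraries were unequal. Their islands held 62321719 and 64531293 ChIP reads in shDCAF5 and 23654421 and 43922947 in shCTRL cells. The part of this in the H3K4me1 gap was not tested. H3K4me1 islands overlapped 93.6% ± 0.249 of shDCAF5-side regions in shDCAF5 cells and 53.3% ± 3.43 in shCTRL cells (SD, n = 2 and 2). On the shCTRL side the shares were 82.3% ± 0.491 and 87.1% ± 1.60, and at other tested regions 87.0% ± 0.0947 and 82.4% ± 1.91 (SD, n = 2 and 2). H3K27ac peaks overlapped 49.2% ± 1.47 of shDCAF5-side regions in shDCAF5 cells (SD, n = 2) and 19.04% in the 1 shCTRL list. On the shCTRL side they overlapped 34.1% ± 0.614 and 70.3%, and at other tested regions 47.7% ± 0.189 and 57.6%. In dTAG cells, H3K27ac peaks overlapped 1.26% ± 0.033 of distal shDCAF5-side regions with V-1 and 0.501% ± 0.082 with DMSO. At other distal regions they overlapped 1.77% ± 0.042 and 0.640% ± 0.016 (SD, n = 2 and 2 each). p300 overlapped 13.04% ± 4.58 of shDCAF5-side regions in shDCAF5 cells and 3.17% ± 1.61 in shCTRL cells (SD, n = 3 and 3), with no overlap between the genotypes (exact permutation p = 0.1, the smallest possible). On the shCTRL side p300 overlapped 8.28% ± 3.03 and 9.26% ± 4.71 (SD, n = 3 and 3; exact permutation p = 0.8). H3K4me3 peaks overlapped 9.07% ± 3.19 of shDCAF5-side regions in shDCAF5 and 1.36% ± 0.109 in shCTRL cells (SD, n = 2 and 2). For H3K4me1 and H3K4me3 the exact permutation p was 0.333, the smallest possible. The 521 regions gained among those called in at least 4 lists had larger differences, with H3K4me1 at 95.5% ± 0.407 against 32.5% ± 3.39 (SD, n = 2 and 2).

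**Figure D3:**
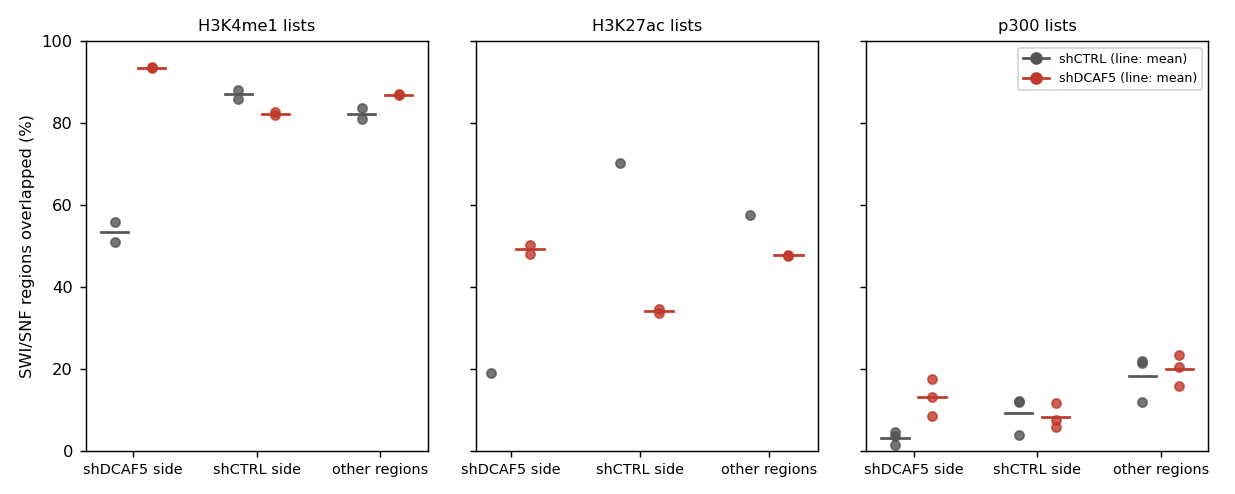
Percent of shDCAF5-side, shCTRL-side and other tested SWI/SNF regions (horizontal axis) overlapped by the peaks or islands of each H3K4me1, H3K27ac and p300 list (vertical axis, %); points are lists, gray for shCTRL and red for shDCAF5, and lines are means where a genotype has more than 1 list. On the shDCAF5 side the H3K4me1 means are 53.3% and 93.6%, and the p300 means are 3.17% and 13.04%.

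For p300, peak number did not differ by more than the spread between lists: 31436 ± 12262 in shCTRL and 32814 ± 7318 in shDCAF5 cells (SD, n = 3 and 3; log2 difference 0.13, exact permutation p = 0.8). The direction turned without shCTRL replicate 1 (-0.26), whose list was the shortest (17278 peaks) and had the lowest recovered background pileup (1.69, against 2.34 to 2.76 in the other p300 lists), and also without shDCAF5 replicate 3 (-0.023), whose list was the longest (39833 peaks). Every shDCAF5 and no shCTRL list called 989 p300 regions, and 352 were the reverse. This direction too turned without shCTRL replicate 1, with 1027 against 2318, where fewer shCTRL than shDCAF5 lists had to agree. Leaving out 1 of the other lists gave 1427 to 2839 for shDCAF5 and 385 to 727 for shCTRL. Of those 989, 153 overlapped an shDCAF5-side SWI/SNF region and 1 an shCTRL-side one. Of the 352, 0 and 1 did. The sides differ in size, with 4537 and 576 regions. The overlap of all p300 regions with them is not given here, so these counts are not read as an enrichment.

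H3K4me1 islands numbered 64196 ± 962 in shDCAF5 and 51992 ± 2737 in shCTRL cells (SD, n = 2 and 2; exact permutation p = 0.333, the smallest possible), covering 396.9 Mb and 360.8 Mb. The ChIP libraries were larger relative to their controls in shDCAF5 (2.02 and 2.07 times) than in shCTRL cells (0.483 and 0.881 times). H3K4me3 peaks numbered 27299 ± 1933 and 24653 ± 276 (SD, n = 2 and 2; exact permutation p = 0.333), while their covered length was lower in shDCAF5 cells, 45.9 Mb against 53.2 Mb. H3K27ac peaks numbered 60543 ± 4805 in shDCAF5 cells (SD, n = 2) and 110807 in the 1 shCTRL list, which was not tested.

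After acute degradation of DCAF5, SWI/SNF peaks were more numerous and more often distal, with 1 list per arm and subunit and no replicate check. After 4 h with 500 nM V-1, ARID1A peaks numbered 66872 against 56581 with DMSO, SMARCC1 peaks 74298 against 67555, and SMARCA4 peaks 90324 against 67027. The distal share was higher with V-1 for each: 57.0% against 49.96% for ARID1A, 60.3% against 55.7% for SMARCC1 and 65.9% against 54.4% for SMARCA4. With equal lists of 56581 peaks the shares were 53.4% against 49.96%, 54.0% against 51.6% and 55.2% against 50.3%. Recovered background pileups were 2.44, 2.85 and 3.34 with V-1 and 3.06, 3.05 and 2.92 with DMSO, so for SMARCA4 the longer list was also the deeper one. Regions called for all 3 subunits with V-1 and in no DMSO list numbered 1948, of which 88.2% were distal, and 154 were the reverse, of which 82.5% were distal. Of all 119416 merged regions of these lists, 75.4% were distal. With equal lists the numbers were 927 and 316. H3K27ac peaks in the dTAG cells numbered 26217 ± 418 with V-1 and 20763 ± 318 with DMSO (SD, n = 2 and 2; exact permutation p = 0.333, the smallest possible), of which 16.4% ± 0.634 and 9.83% ± 0.435 were distal. With equal H3K27ac lists of 20538 peaks the distal shares were closer, 11.4% and 11.5% with V-1 against 9.85% and 9.52% with DMSO.

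The regions that leaned to shDCAF5 were more often called only with V-1. Such regions were few, and many of that side already had peaks with DMSO. At least 1 DMSO list had a peak in 44.4% of the shDCAF5 side, 48.6% of the shCTRL side and 49.0% of the other tested regions. Within distal regions, all 3 DMSO lists had a peak in 20.8%, 10.8% and 12.5%. All 3 V-1 lists and no DMSO list had a peak in 2.25% of the shDCAF5-side regions (102 of 4537), in 0.868% of the shCTRL-side regions (5 of 576) and in 1.14% of the other tested regions (1029). The odds ratio of the shDCAF5 side against other regions was 1.996 (Fisher exact p = 1.59e-09) and within distal regions 1.74 (Fisher exact p = 1.20e-06). Against the shCTRL side it was 2.63 (Fisher exact p = 0.0291), and within distal regions 2.37 (Fisher exact p = 0.0526). These tests run across regions, which are not independent replicates. All 3 DMSO lists and no V-1 list had a peak in 0.0661% of the shDCAF5 side, 0.174% of the shCTRL side and 0.0797% of the others. More V-1 than DMSO lists had a peak in 1194 of the 4537 regions on the shDCAF5 side and in 185 of the 576 on the shCTRL side (odds ratio 0.755, Fisher exact p = 0.00381). More DMSO than V-1 lists had a peak in 264 and 77 of them (odds ratio 0.4004, Fisher exact p = 7.13e-10). Against the other tested regions the shDCAF5 side had more V-1 lists more often (odds ratio 1.33, Fisher exact p = 1.05e-15; within distal regions 1.10, Fisher exact p = 0.00736) and more DMSO lists less often (0.749, Fisher exact p = 3.91e-06).

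BRD9 lists in shCTRL cells held 11312 and 15400 peaks, of which 80.3% and 78.8% were promoter-like. SMARCA4 replicate 3 peaks overlapped 95.7% and 95.1% of them, SMARCA4 replicate 1 peaks 79.1% and 73.7%, and ARID1A replicate 1 peaks 70.5% and 67.4%. The longer ARID1A lists overlapped more, 89.7% and 87.7% in replicate 2 and 91.3% and 89.9% in replicate 3. For SMARCC1 the overlaps were 75.1% and 71.6% in replicate 1, 83.3% and 82.6% in replicate 2, and 94.8% and 93.9% in replicate 3. BRD9 peaks overlapped 0.926% and 1.39% of the shDCAF5-side regions, 1.56% and 2.95% of the shCTRL-side regions, and 7.27% and 10.3% of the other tested regions. Within distal regions alone the overlaps were closer, 0.910% and 1.31% on the shDCAF5 side against 1.32% and 2.11% at other regions. The shDCAF5 side was chosen for few calls in shCTRL cells, the source of both BRD9 lists. Its low overlap therefore says nothing particular about BRD9.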

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

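Chosen only after the result was seen were the tests on the library labelled shCTRL SMARCC1 replicate 2, the unadjusted threshold that defines the 2 sides, the look at how splits divide replicate 1 lists, and the H3K4me1 check of ARID1A.

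H3K27ac peak number moved in opposite directions in the 2 systems: the mean log2 difference was -0.87 for shDCAF5 against shCTRL, with 63940 and 57145 peaks against 110807, and 0.34 for V-1 against DMSO, with both V-1 lists above both DMSO lists. With a -log10 q of at least 5 the differences were -0.68 for shDCAF5 and 0.40 for V-1, and by covered length -0.39 and 0.65. The difference between the systems was not tested. The shRNA comparison has 1 shCTRL list, and the samples come from different series of library numbers. With equal list length the distal share of the shDCAF5 lists was below that of shCTRL by a difference of -2.99 percentage points, compared with 15.1 points with all peaks (80.3% in shCTRL and 65.2% in shDCAF5). The distal share is another quantity than the peak number and does not decide why the number of peaks moved, so the cause stays open, and no biological explanation was tested.

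More regions leaned to shDCAF5 (4537) than to shCTRL (576). Of 100 splits of the 17 lists within antibody, 13 gave as many regions on one side, the real one included, and the highest other gave 11011, so chance is not excluded by this count. None of the 12 other splits had more than 2 of the 6 replicate 1 lists on its larger side, which points to the structure of the 2 series; among the 29 splits that, like the real one, put 3 replicate 1 lists on each side, the highest gave 3286 and 0 gave as many. Those splits move lists of each antibody independently, although lists with one replicate number may share chromatin. When whole replicate numbers were moved, 4 of the 9 other splits gave more than 4537 (9329, 11060, 12452 and 20452), each with both replicate 1 sets on one side. Only 6 splits are balanced for replicate 1, with the real one the highest and 1571 the next, which are too few to exclude chance. The ratio of the sides was 2.243 with equal list length and 5.93 without replicate 1, so neither setting made the sides even. The fall from 7.88 to 2.243 leaves room for list length as a part. Uneven sides are not particular to the genotypes. Some other splits with 3 replicate 1 lists on each side gave 1935 to 46 or 3286 to 382 regions, and others were closer (219 to 156). No split was run with equal list length, so these ratios do not decide the cause. Loss of DCAF5 as the biological explanation stays open as a hypothesis: the odds ratio of V-1-only calls at distal regions against the shCTRL side was 2.37 with a Fisher exact p of 0.0526, while regions with more V-1 than DMSO lists were less frequent than on the shCTRL side (odds ratio 0.716, Fisher exact p = 0.00106, distal regions). Distal regions with more DMSO than V-1 lists were also less frequent on the shDCAF5 side (odds ratio 0.401, Fisher exact p = 4.68e-09). The 2 directions held 1138 and 251 distal regions on the shDCAF5 side, and 170 and 68 on the shCTRL side.

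The library labelled shCTRL SMARCC1 replicate 2 stood apart from the 7 other shCTRL lists. It had peaks in 73.9% of 1919 regions that ARID1A and SMARCA4 lists called mainly in shDCAF5 and in 21.0% of 157 called mainly in shCTRL, and its log2 ratio of these shares lay 0.50 above the lowest of the shDCAF5 SMARCC1 lists. Its low depth is argued against as the cause, since it called 62.1 percentage points more of the 1919 regions than shCTRL SMARCC1 replicate 3 did. Its log2 ratio of H3K4me1 regions found in shDCAF5 alone to those found in shCTRL alone was 1.44, with the 7 others at -2.16 to -0.79 and the shDCAF5 lists at 1.57 to 4.40; with equal list length it was 2.36, within the shDCAF5 range of 2.13 to 4.40. The same ratio on p300 regions was 0.28 with all peaks, where the 7 others (-0.26 to 0.36) and the shDCAF5 lists (0.083 to 1.61) overlap, and 0.97 with equal list length (-0.28 to 0.45 and 0.45 to 1.61). A wrong label and chromatin or reads of both genotypes cannot be told apart by these values; no shDCAF5 SMARCC1 list was out of place as a partner of a swap, and its distal share with equal list length, 22.8%, was close to the 23.6% of shCTRL replicate 3.

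The peaks of the lists labelled shDCAF5 ARID1A replicates 2 and 3 carry names that read shCTRL. A wrong label is argued against: in regions defined by SMARCC1 and SMARCA4 lists, the lower of their log2 ratios of shDCAF5-type to shCTRL-type calls was 1.98 above the highest of the shCTRL ARID1A lists of replicates 2 and 3. The values were 2.59 and 1.16 against -0.82 and -1.08, and they rest on 40 shCTRL-type regions. With H3K4me1 regions in place of SWI/SNF regions their log2 ratios were 1.88 and 1.57.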

How the results depend on the processing

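Settings added after the data were seen were leaving out the 2 lists named shCTRL, leaving out the 2 lists of lowest background, peaks covering at least 50% of a region, and equal list length without shCTRL SMARCC1 replicate 2. The SWI/SNF peak number turned direction with replicates 2 and 3 alone (-0.0086326), covered length (-0.033181) and no lists named shCTRL (-0.21749), with a leave-one-out range of -0.16704 to 0.39624. Per subunit the leave-one-out ranges were -0.65865 to 0.34031 (ARID1A), -0.2382 to 0.86924 (SMARCC1) and -0.65765 to 1.0322 (SMARCA4, -0.18207 with replicates 2 and 3 alone). The distal share passed the threshold only with equal list length (10.964) and with that and no shCTRL SMARCC1 replicate 2 (11.606). It was -0.45931 with replicates 2 and 3 alone and -0.50243 to 16.225 leaving out lists. By subunit, replicates 2 and 3 alone gave -2.8167 (ARID1A, -8.8589 without the lists named shCTRL) and -5.1149 (SMARCA4), and leave-one-out ranges were -9.2543 to 11.574, -2.8653 to 23.71 (SMARCC1) and -18.135 to 32.048. Gained regions numbered 1304 with equal list length, 521 in at least 4 libraries, 408 without the 2 lists of lowest background, 1285 with the 2 choices together, and 0 to 383 leaving out lists. Lost regions numbered 142 and 105 in the 2 equal-length settings. The shDCAF5 side held 2886 regions with replicates 2 and 3 alone, 2856 with 50% cover and 2637 to 4689 leaving out lists. The shCTRL side held 1446 with equal list length, 319 with 50% cover, 166 without the lists named shCTRL, 1337 with the 2 choices together and 74 to 601 leaving out lists. The p300 peak number ranged from -0.25609 to 0.32344 leaving out lists, and H3K4me3 covered length gave -0.21332. Apart from the parts of the shCTRL-side and shDCAF5-side falls that are set by the test, the causes were not tested. With the replicate block, the peak number difference was 0.019678 and the distal share 5.6854, no region was gained or lost, and the sides held 4305 and 551. Same-number correlations between genotypes ran from -0.00709 to 0.161, and different-number ones from -0.166 to 0.0671. The highest of each antibody was the replicate 1 pair (ARID1A 0.161, SMARCC1 0.123, SMARCA4 0.145), which points to the 2 series. The main tests did not take numbers as pairing and moved lists across the 2 series. Acute overlap odds ratios were 1.5161 with at least 2 V-1 lists and 2.6905 with equal length. Promoters by annotated start sites and gene windows were not run for want of an annotation of the build, and the planned 50% overlap moves nothing, since each peak lies within its region. Depth could be compared only among the 27 lists with a recovered background, and its effect on the counts was not tested.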

Other observations

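The per-chromosome values and the splits with 1 replicate 1 list on each side were looked at only after the results were seen, and the test on replicate 1 regions was added after the region counts were seen but before its own result.

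Regions chosen in replicate 1 alone were also called unequally in lists that had no part in the choice. Of the tested regions, 1881 had peaks in all 3 shDCAF5 and no shCTRL lists of replicate 1, and 81.7% of them were distal. In replicates 2 and 3 the shDCAF5 lists called 98.6% ± 2.15 of them and the shCTRL lists 64.1% ± 16.2 (SD, n = 6 and 5), and the lowest shDCAF5 list, at 94.3%, lay above the highest shCTRL list, at 91.0%. The mean difference over the subunits was 35.1 percentage points (exact permutation within antibody, p = 0.00926, the smallest of 108 arrangements), which argues against a difference private to replicate 1. The 610 regions with peaks in all 3 shCTRL and no shDCAF5 lists of replicate 1 were 11.6% distal, and in replicates 2 and 3 they were called at 98.0% ± 3.44 in shCTRL and 95.0% ± 9.24 in shDCAF5 lists (SD, n = 5 and 6; exact permutation p = 0.528). Lists of different subunits with one replicate number may share chromatin, so this p may be too small. The first set is consistent with a gain of mostly distal sites that recurs between the series, as a hypothesis. The second set decides nothing, since nearly all of its regions were called in the longer lists of both genotypes, as were those called in all 6 replicate 1 lists (99.9% and 99.8%).

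Chromosome 19 had the lowest ratio of shDCAF5-side to shCTRL-side regions, 78 to 64 or 1.22, of the 23 chromosomes, followed by chromosome 17 with 167 to 51. Chromosome 4 had 258 to 14 and chromosome 18 had 103 to 8. No test was run on these ratios.

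The counts of regions called in every list of one genotype and none of the other were set against the 10 splits of each 6 lists. For ARID1A 1791 regions in both directions were found, and 2 of the 10 splits gave as many, with 7879 in the highest other. For SMARCC1 the count was 677, 5 of the 10 splits gave as many, and the highest other gave 7526. Chance is not excluded for either, and the larger counts came from splits with both replicate 1 shCTRL and shDCAF5 lists on one side, which points to the 2 series. The 5 other splits with 1 replicate 1 list on each side gave at most 166 regions for ARID1A and 135 for SMARCC1, and are too few for a share under 0.05. For p300 the count was 1341 and the highest other split gave 1017, so 1 of the 10 splits gave as many; 10 splits are too few for a share under 0.05.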
